A study of Homo sapiens with 8 samples.

How the data were processed

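RNA was measured by sequencing in 8 libraries from M059K and H4, established human glioma cell lines grown in culture. Each line had been treated for 72 h with 5 µM 6-thio-dG or with DMSO, the solvent. 6-thio-dG is a thiopurine nucleoside that telomerase can add to chromosome ends. The line and the treatment gave 4 groups of 2 libraries each. Per the labels, total RNA was extracted with a Qiagen RNeasy Mini kit and libraries followed a standard Illumina protocol.

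The deposited files hold a raw read count per Ensembl gene for each library, with 18952 genes and 5 lines for unassigned reads. The submitters' processing notes name FastQC 0.11.5, Trim Galore 0.6.5, the GRCh38 build and counting with HTSeq 0.12.4. The aligner, the annotation release, the strand setting and the way RNA was selected (poly(A) or depletion) are not given in the sources used here. Counts of genes that overlap on opposite strands are therefore uncertain. Reads of close paralogs (histones, HLA genes, keratins, SPRR2 genes, protocadherins) can be shared between genes or left out as not unique. Symbols were assigned by the current Ensembl identifier for 18749 genes and by GENCODE release 29 for 44, and 159 had none. Positions came from GENCODE release 29 on GRCh38. By that annotation 18727 genes were protein-coding and 0 were mitochondrial, so mitochondrial genes and TERC, the RNA of telomerase, were not analysed here.

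Counts assigned to genes ran from 14165835 to 25382332 per library, 65.1 to 78.8% of all counted reads. A floor of 3 counts per library was used for values at 0. It corresponds to 0.165 CPM in M059K DMSO, 0.196 CPM in M059K 6-thio-dG, 0.162 CPM in H4 DMSO and 0.164 CPM in H4 6-thio-dG, each the higher of its group's 2 libraries. Where a group held 0 counts, the fold is a lower bound against this floor. Where it held 1 to 3 counts, the ratio is given with a 95% exact conditional interval on the counts. Floors and intervals cover counting error only.

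Genes were kept by filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total 15), which left 14618. Library sizes were scaled by TMM, and quasi-likelihood models with 1 coefficient per group were fitted to all 8 libraries. The residual degrees of freedom were 4 and the common biological coefficient of variation was 0.0678. The comparisons were 6-thio-dG against DMSO in each line, the difference of those responses (H4 minus M059K, the line by treatment interaction) and H4 against M059K in DMSO. P-values were adjusted by the Benjamini-Hochberg method over the 14618 genes of a comparison, with a threshold of 0.05. The standard error of a log2 fold change was derived as its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD over the 2 libraries of a group.

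Before the data were examined, 39 gene lists were written, and 38 had at least 3 tested members. They cover p53 targets, replication, mitosis, DNA repair and checkpoints, telomeres, purine metabolism, apoptosis, interferon and cytokine responses, stress responses, metabolism, extracellular matrix, histones, ribosomes, lysosomes, glioma subtypes and cell types. Each was tested in every comparison with camera in limma 3.58.1 (preset correlation 0.01), adjusted over the 38 lists. Member counts use p-values adjusted over all genes and, separately, adjusted over the list alone. Camera with an estimated correlation and fry were run beside it. Camera with an estimated correlation gave higher p-values even where the estimate lay below the preset. For p53 targets in H4 the estimate was 0.0085, and the unadjusted camera p was 2.46e-14 with the preset and 0.00147 with the estimate. A call lost under this setting therefore does not by itself show that the members of a list vary together. Fry asks whether a list's genes move one way and does not compare them with other genes.

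Genes named in the text followed a rule fixed before the data were examined. It took the 10 largest changes each way for a treatment comparison, 6 each way for the interaction and 8 each way for DMSO. Eligible genes had an adjusted p under 0.05, a mean of at least 5 CPM over the libraries compared, and, for treatment, both treated libraries beyond both DMSO libraries. Up to 4 members per list and 8 genes related to the drug (TERT, CDKN1A, MDM2, GDF15, PRKDC, MKI67, HPRT1, SAMHD1) were also named. A few genes that the rule selects are not reported.

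Alternatives were RLE factors, library size alone, no filter, a stricter filter (at least 5 CPM in at least 2 libraries), a replicate block, each library left out in turn, DESeq2 1.42.0, glmTreat against a 1.5-fold change and fits of only the 4 libraries compared. Removing each library's GC trend (lowess, span 0.3), testing families of gene symbols, a list of histone variants and positions near chromosome ends were added after the data were examined. GC content was known for 99.9% of tested genes. The procedure was tested on simulated data with changes planted in 200 genes, far fewer than were called in the real comparisons. In M059K it recovered 30, 76, 86 and 94% of genes changed 1.25, 1.5, 2 and 4-fold, and in the interaction 8, 42, 78 and 88%. Of 100 simulated lists without a change, 3 had a camera p under 0.05. Simulated genes were drawn independently, while real lists had estimated correlations as high as 0.406 (ribosome biogenesis, M059K). The simulation therefore does not test the preset correlation on lists whose members vary together. R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used. Shares of unassigned reads were compared by an exact permutation test of treatment labels within each line (36 arrangements), with Benjamini-Hochberg adjustment over 3 shares.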

Results

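Read counts per gene were given for M059K and H4 glioma cells after 72 h in 5 µM 6-thio-dG or in DMSO, with 2 libraries in each of the 4 groups. Counts on genes were 25382332 and 19908444 in M059K DMSO, 18573859 and 14165835 in M059K 6-thio-dG, 19157494 and 18985431 in H4 DMSO, and 17513905 and 17743298 in H4 6-thio-dG. Between 15121 and 15955 genes had a count above 0. The 10 most counted genes took 2.95 to 6.17% of gene counts, and the most counted were COL1A1 (M059K DMSO), THBS1 (M059K 6-thio-dG), FTL (H4 DMSO) and GDF15 (H4 6-thio-dG). In a principal component analysis of 500 genes, the first component (92.3% of variance) separated the lines and the next (5.0%) separated treated from DMSO libraries in both. Replicates differed by more than counting error, with a chi-square per degree of freedom of 4.26 to 8.67. The sources do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries.

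The first comparison asks how 6-thio-dG changed transcripts in M059K. By camera, extracellular matrix and interferon response genes were lower, and p53 target, integrated stress response and DNA replication genes were higher. With an estimated correlation only the matrix call remained among these (adjusted p 0.0437), and the others were at 0.153 to 0.207. ACTA2, smooth muscle actin, fell by 5.58 ± 0.10 on the log2 scale (SE), from 446 ± 14 to 9.30 ± 0.71 CPM (SD, n = 2). SULF2, an extracellular heparan sulfate sulfatase, fell by 6.32 ± 0.14 (SE), from 191 ± 18.0 to 2.29 ± 1.21 CPM. CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, rose by 2.19 ± 0.08 (SE), from 69.5 ± 3.31 to 316 ± 5.11 CPM. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 4.52 ± 0.17 (SE), from 3.93 ± 0.20 to 91.0 ± 9.24 CPM.

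In all, 9148 of 14618 genes (62.6%) had an edgeR adjusted p under 0.05, 4394 higher and 4754 lower. Of these, 1059 rose and 2099 fell at least 2-fold. By rule, the largest rises were SPINK1, ANGPTL4, PRRG4, CXCL8, IL1RL1, SERPINB2, QRFP, IL24, MAFF and CMYA5, which encode among others the cytokines CXCL8 (3.53 ± 0.16, SE) and IL24 (3.26 ± 0.21) and the protease inhibitors SPINK1 (5.09 ± 0.38) and SERPINB2. The largest falls were SULF2, TRIL, SCUBE1, OLFML2B, ACTA2, MXRA5, OMD, CH25H, NFE2 and L1CAM, from -6.32 to -4.94. With library size alone as the scaling, the median over all genes moved by 0.25 (log2) and 6208 of 9616 called genes were higher (64.6%, against 48.0% with TMM). Small changes in M059K are therefore relative to the TMM scale.

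Among the genes related to the drug, TERT, the catalytic subunit of telomerase, rose by 0.73 ± 0.17 (SE) in M059K, from 19.7 ± 1.34 to 32.8 ± 4.50 CPM. MDM2, the p53 ubiquitin ligase, rose by 0.90 ± 0.09, and GDF15, a stress-induced cytokine, by 1.96 ± 0.09. PRKDC, the catalytic subunit of DNA-dependent protein kinase, fell by 0.998 ± 0.07, from 777 ± 46.9 to 389 ± 7.41 CPM. SAMHD1, a dNTP hydrolase, fell by 1.04 ± 0.09. HPRT1, which activates thiopurine bases, rose by 0.39 ± 0.11, but its edgeR adjusted p was 0.16 without M059K 6-thio-dG replicate 2 (log2 0.17). MKI67, a proliferation marker, fell by 0.36 ± 0.09 with an adjusted p of 0.0014. That p was 0.132 without M059K 6-thio-dG replicate 2 (-0.13), 0.326 with library size alone (-0.10) and 0.078 by DESeq2. These genes lie at chromosome 5, 1253147 to 1295069 (TERT, ENSG00000164362), chromosome 6, 36676460 to 36687339 (CDKN1A, ENSG00000124762), chromosome 12, 68808176 to 68850686 (MDM2, ENSG00000135679), chromosome 19, 18374731 to 18389176 (GDF15, ENSG00000130513), and chromosome 8, 47773108 to 47960183 (PRKDC, ENSG00000253729), on GRCh38.

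Of the 38 lists, camera called 9 higher and 11 lower in M059K. Only extracellular matrix and histone genes were also called with an estimated correlation. Member counts adjusted over the list alone were the same as those over all genes for each list called in M059K, except where given.

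DNA replication and E2F target genes rose in M059K (35 of 46 higher, 1 lower, 10 not called, median 0.56), with a camera adjusted p of 1.00e-08 and adjusted p = 0.207 with an estimated correlation. Examples were the transcription factor genes E2F2 (1.83) and E2F1 (1.48), CCNE2 (1.66) and the licensing factor CDT1 (1.41). G2/M and mitosis genes fell (1 of 44 higher, 37 lower, 6 not called, median -0.74, adjusted p 7.78e-12 and adjusted p = 0.179 with an estimated correlation), among them the mitotic kinase PLK1 (-2.12), HMMR (-2.12), KIF20A (-1.94) and CCNB1 (-1.91). Homologous recombination and Fanconi genes rose (19 of 30 higher, 3 lower and 8 not called, or 19 and 4 adjusted over the list alone, median 0.57, adjusted p 0.000399 and adjusted p = 0.179 with an estimated correlation), with EXO1 at 1.43 and BRCA1 at 1.34. p53 target genes rose (19 of 34 higher, 10 lower, 5 not called, median 0.48, adjusted p 0.000468 and adjusted p = 0.153 with an estimated correlation), with PLK3 at 1.72 and AEN at 1.68 beside CDKN1A and GDF15. Apoptosis regulators rose (19 of 27 higher, 4 lower, 4 not called, median 0.39, adjusted p 0.00664 and adjusted p = 0.154 with an estimated correlation), with BCL2 at 2.31 and BIRC3 at 1.82, while TNFSF10 fell by 3.67. Telomerase and telomere genes rose (14 of 22 higher, 3 lower, 5 not called, median 0.35, adjusted p 0.0419 and adjusted p = 0.179 with an estimated correlation), with CTC1 at 1.25, PINX1 at 1.17 and TERF2 at 0.93. That call was not reached with the stricter filter (adjusted p 0.055).

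Histone genes fell in M059K (0 of 16 higher, 14 lower, 2 not called, median -2.49, camera adjusted p 1.13e-09, and 0.0437 with an estimated correlation), with H3C10 at -4.14, H1-2 at -3.34 and H2BC21 at -3.18. Extracellular matrix and mesenchymal genes fell (0 of 31 higher, 28 lower, 3 not called, median -2.14, adjusted p 3.94e-55, and 0.0437 with an estimated correlation), with COL3A1 at -4.41, COL1A2 at -3.79 and COL6A3 at -3.50. COL3A1, a fibrillar collagen, went from 5545 ± 507 to 261 ± 25.7 CPM (SD, n = 2). Pericyte and fibroblast markers fell (1 of 7 higher, 5 lower, 1 not called, median -2.02, adjusted p 2.21e-06 and adjusted p = 0.0927 with an estimated correlation), with PDGFRB at -3.49 and LUM at -2.02.

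Type I interferon response genes fell in M059K (2 of 37 higher, 31 lower, 4 not called, median -1.33, camera adjusted p 1.17e-15 and adjusted p = 0.179 with an estimated correlation), with MX2 at -3.77, IFIT1 at -3.50, EPSTI1 at -2.89 and IFITM1 at -2.54. MHC class I presentation genes fell (1 of 15 higher, 14 lower, 0 not called, median -0.86, adjusted p 3.05e-06 and adjusted p = 0.179 with an estimated correlation), with PSMB9 at -1.73, TAP1 at -1.43 and HLA-B at -1.22. NF-kB and cytokine genes rose (15 of 22 higher, 1 lower, 6 not called, median 0.63, or 0.76 with 1 member at or under the floor left out, adjusted p 0.00263 and adjusted p = 0.179 with an estimated correlation), with IL1A at 2.54 beside CXCL8 and IL24.

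Early response and MAPK feedback genes rose in M059K (15 of 22 higher, 3 lower, 4 not called, median 0.83, camera adjusted p 3.86e-05 and adjusted p = 0.153 with an estimated correlation). Integrated stress response genes rose (15 of 30 higher, 6 lower, 9 not called, median 0.21, adjusted p 0.000542 and adjusted p = 0.179 with an estimated correlation), with SLC3A2 at 3.21, ATF3 at 2.61 and PPP1R15A at 2.52 while ALDH1L2 fell by 1.74. Ribosome biogenesis and MYC target genes rose (17 of 25 higher, 3 lower and 5 not called, or 17 and 4 adjusted over the list alone, median 0.43, adjusted p 0.00899 and adjusted p = 0.543 with an estimated correlation). Cytosolic ribosomal protein genes fell (2 of 50 higher, 38 lower and 10 not called, or 3 and 39 adjusted over the list alone, median -0.38, adjusted p 0.000946 and adjusted p = 0.528 with an estimated correlation). Cholesterol synthesis genes fell (0 of 25 higher, 23 lower, 2 not called, median -0.77, adjusted p 1.00e-06 and adjusted p = 0.153 with an estimated correlation), with LSS at -1.96 and DHCR7 at -1.70. Endoplasmic reticulum chaperone genes fell (3 of 20 higher, 14 lower, 3 not called, median -0.47, adjusted p 0.000468 and adjusted p = 0.179 with an estimated correlation), with PDIA4 at -2.08 and HSP90B1 at -1.56 while DNAJB9 rose by 1.71.

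Secreted proteases and growth factor binding proteins of the senescence secretome were called lower in M059K (8 of 26 higher, 15 lower, 3 not called, median -0.44, camera adjusted p 0.00682 and adjusted p = 0.179 with an estimated correlation), with SERPINB2 at 3.43 and IGFBP3 at -2.75. Their adjusted p was 0.0806 without M059K 6-thio-dG replicate 1, 0.101 and 0.0991 without H4 DMSO replicate 1 or 2, and 0.093 and 0.106 without H4 6-thio-dG replicate 1 or 2. Mesenchymal glioma markers were called lower (3 of 17 higher, 9 lower, 5 not called, median -0.19, which became 0.06 with library size alone, adjusted p 0.0358 and adjusted p = 0.179 with an estimated correlation), with CHI3L1 at -3.31. Leaving out any 1 of the 8 libraries ended that call, at adjusted p from 0.0693 (without M059K DMSO replicate 2) to 0.152 (without H4 DMSO replicate 1).

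**Figure D1:**
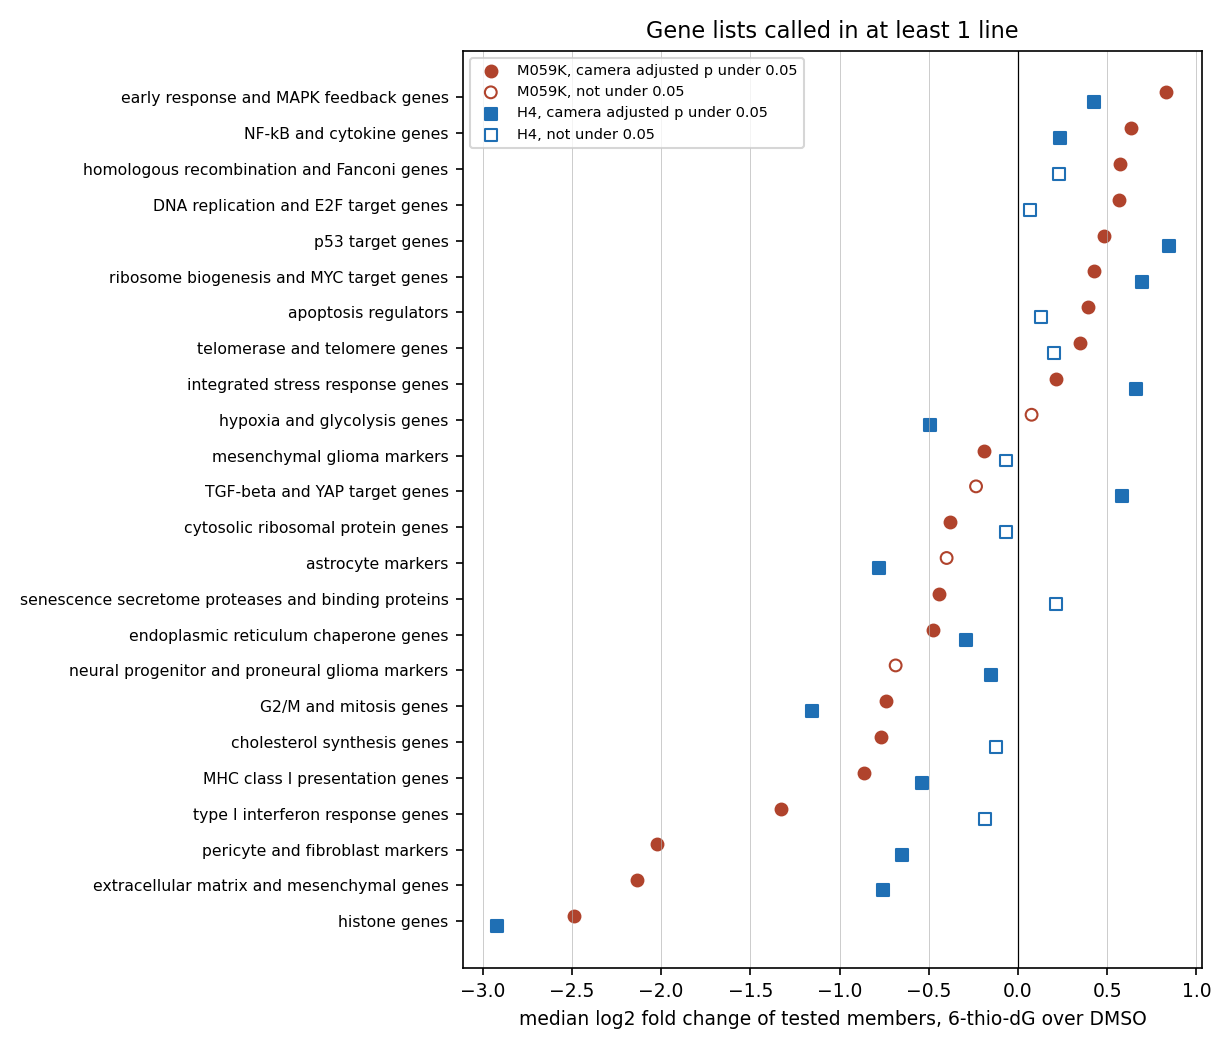
Median log2 fold change, 6-thio-dG over DMSO, of the gene lists called by camera in at least 1 line (circles M059K, squares H4; filled where the camera adjusted p was under 0.05), relative to TMM scaling. Histone genes had the lowest medians in both lines, -2.49 in M059K and -2.92 in H4, and the M059K median of mesenchymal glioma markers becomes 0.06, that of TGF-beta and YAP targets 0.02 and the H4 median of cytosolic ribosomal proteins 0.045 with library size alone.

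The next comparison asks the same question in H4. By camera, p53 target, integrated stress response and TGF-beta or YAP target genes were higher and histone genes lower, also with an estimated correlation. Mitosis, extracellular matrix and hypoxia genes were called lower too, but these calls were lost with an estimated correlation (adjusted p 0.0814, 0.0892 and 0.0892). GDF15 rose by 3.21 ± 0.08 (SE), from 902 ± 42.8 to 8342 ± 306 CPM (SD, n = 2). ANKRD1, a YAP-induced ankyrin repeat protein (chromosome 10, 90912096 to 90921276), rose by 6.79 ± 0.13, from 3.35 ± 1.06 to 372 ± 28.6 CPM. COL3A1 fell by 6.96 ± 0.12, from 1190 ± 144 to 9.55 ± 1.22 CPM. CA9, a carbonic anhydrase induced by hypoxia, fell by 4.57 ± 0.21, from 52.2 ± 16.6 to 2.19 ± 0.16 CPM.

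In H4, 8100 of 14618 genes (55.4%) had an edgeR adjusted p under 0.05, 3982 higher and 4118 lower, of which 1074 rose and 1391 fell at least 2-fold. The largest rises by rule included SPRR2D, LCN2, KRT75, KRT34, ANKRD1, KLHDC7B, SLAMF7, ESM1 and IL24. Counts of SPRR2D, an epidermal envelope protein, were 716-fold higher (95% counting interval 198 to 5916) and those of the keratin KRT34 247-fold higher (84.0 to 1198). KRT75, a hair follicle keratin, rose by 7.85 ± 0.30 (SE), from 0.27 ± 0.31 to 63.9 ± 9.63 CPM. The largest falls were PLEKHS1, PI15, TP63, DCN, TNFSF10, COL3A1, ITGA8, LRRC17, POSTN and PCDH18. PLEKHS1 was at least 98.0-fold lower, and counting intervals for the ratio to DMSO were 719 to 10200-fold lower for PI15, 116 to 25720 for TP63, 99.1 to 2971 for DCN and 94.9 to 2847 for TNFSF10. With library size alone the median over all genes moved by 0.11 (log2) and 5061 of 8359 called genes were higher (60.5%, against 49.2% with TMM).

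TERT rose by 1.49 ± 0.22 (SE) in H4, from 3.89 ± 1.75 to 10.9 ± 2.50 CPM (SD, n = 2). CDKN1A rose by 1.58 ± 0.07, from 274 ± 17.0 to 818 ± 73.7 CPM, and MDM2 by 1.25 ± 0.08. MKI67 fell by 1.41 ± 0.10, from 436 ± 14.9 to 164 ± 11.8 CPM. HPRT1 was not called (0.12 ± 0.10, edgeR adjusted p 0.321), except with library size alone (0.24). PRKDC rose by 0.17 ± 0.07 with an adjusted p of 0.0344, which was 0.101 and 0.0915 without H4 DMSO replicate 1 or 2, 0.192 without H4 6-thio-dG replicate 1 and 0.0542 without M059K DMSO replicate 2. SAMHD1 fell by 0.23 ± 0.10 with an adjusted p of 0.0488, which was 0.194 and 0.128 without H4 DMSO replicate 1 or 2, 0.0843 and 0.272 without H4 6-thio-dG replicate 1 or 2, 0.0583 without M059K DMSO replicate 1, 0.313 with library size alone and 0.104 by DESeq2.

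Of the 38 lists, camera called 6 higher and 9 lower in H4, and 4 of these were also called with an estimated correlation. Counts adjusted over the list alone matched those over all genes for lists called in H4, except where given. p53 target genes rose (27 of 34 higher, 5 lower, 2 not called, median 0.84, camera adjusted p 2.33e-13, and 0.0429 with an estimated correlation). Integrated stress response genes rose (27 of 30 higher, 2 lower, 1 not called, median 0.66, adjusted p 5.33e-17, and 0.0429 with an estimated correlation), with ATF3 at 3.19, the hormone FGF21 at 3.18, PPP1R15A at 3.16 and STC2 at 2.09. TGF-beta and YAP target genes rose (16 of 23 higher, 4 lower, 3 not called, median 0.58, adjusted p 1.50e-07, and 0.0429 with an estimated correlation), with INHBA at 2.37 and CCN2 at 1.96 beside ANKRD1. Histone genes fell (0 of 16 higher, 14 lower, 2 not called, adjusted p 1.26e-08, and 0.0429 with an estimated correlation). Their median was -2.92 as fitted and -2.58 with 2 members at their bounds and 1 left out. H1-3 was at least 1.65-fold lower and HIST1H3B at least 3.96-fold lower.

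G2/M and mitosis genes fell in H4 (0 of 44 higher, 43 lower, 1 not called, median -1.15, camera adjusted p 8.95e-32 and adjusted p = 0.0814 with an estimated correlation), with KIF20A at -3.28 and ASPM at -2.24. DNA replication and E2F target genes went both ways (18 of 46 higher, 13 lower, 15 not called, median 0.07, adjusted p 0.848). Ribosome biogenesis and MYC target genes rose (23 of 25 higher, 0 lower, 2 not called, median 0.69, adjusted p 2.83e-08 and adjusted p = 0.295 with an estimated correlation), with RRP12 at 1.48 and RRP9 at 1.40. Early response and MAPK feedback genes were called higher (15 of 22 higher, 5 lower, 2 not called, median 0.42, adjusted p 0.00375 and adjusted p = 0.201 with an estimated correlation), although EGR1 was at -4.84 and FOS at -3.34. Their adjusted p was 0.055 without H4 DMSO replicate 1, 0.05003 without H4 6-thio-dG replicate 2 and 0.0564 without the filter on low counts, all above the threshold. NF-kB and cytokine genes were called higher (7 of 22 higher, 2 lower, 13 not called, median 0.23, adjusted p 0.0188 and adjusted p = 0.227 with an estimated correlation). Leaving out any 1 of the 8 libraries ended this call, at adjusted p from 0.0589 (without M059K DMSO replicate 1) to 0.234 (without H4 DMSO replicate 1).

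Extracellular matrix and mesenchymal genes fell in H4 (6 of 31 higher, 22 lower and 3 not called, or 7 and 22 adjusted over the list alone, median -0.76, camera adjusted p 7.37e-16 and adjusted p = 0.0892 with an estimated correlation), with POSTN at -5.86 and FN1 at -2.97 beside COL3A1. Hypoxia and glycolysis genes fell (4 of 28 higher, 17 lower, 7 not called, median -0.50, adjusted p 0.000145 and adjusted p = 0.0892 with an estimated correlation), with EGLN3 at -3.16, PFKFB4 at -1.59 and GAPDH at -1.07 beside CA9. MHC class I presentation genes fell (2 of 15 higher, 13 lower, 0 not called, median -0.54, adjusted p 0.000538 and adjusted p = 0.295 with an estimated correlation). Type I interferon response genes were not called (5 of 37 higher, 17 lower, 15 not called, median -0.18, adjusted p 0.0903). Endoplasmic reticulum chaperone genes were called lower (5 of 20 higher, 12 lower, 3 not called, median -0.29, adjusted p 0.0255 and adjusted p = 0.389 with an estimated correlation), with an adjusted p of 0.0566 without H4 6-thio-dG replicate 2.

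Astrocyte markers were called lower in H4 (1 of 10 higher, 6 lower, 3 not called, median -0.78, camera adjusted p 0.0158 and adjusted p = 0.254 with an estimated correlation), with GJA1 at -1.87 and APOE at -1.47. Neural progenitor and proneural glioma markers were called lower (5 of 13 higher, 6 lower, 2 not called, median -0.15, adjusted p 0.0255 and adjusted p = 0.201 with an estimated correlation), with SOX2 at -4.08, NES at -3.53 and PDGFRA at -2.74. Leaving out any 1 of the 8 libraries ended the proneural call, at adjusted p from 0.102 (without M059K DMSO replicate 1) to 0.280 (without H4 6-thio-dG replicate 2). Pericyte and fibroblast markers were called lower (3 of 7 higher, 3 lower, 1 not called, median -0.65, adjusted p 3.92e-05 and adjusted p = 0.0767 with an estimated correlation), with LUM at -3.64 and ABCC9 at 2.49. Their adjusted p was 0.081 and 0.0661 without M059K 6-thio-dG replicate 1 or 2, 0.0835 and 0.121 without H4 DMSO replicate 1 or 2, and 0.145 and 0.210 without H4 6-thio-dG replicate 1 or 2.

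**Figure D2:**
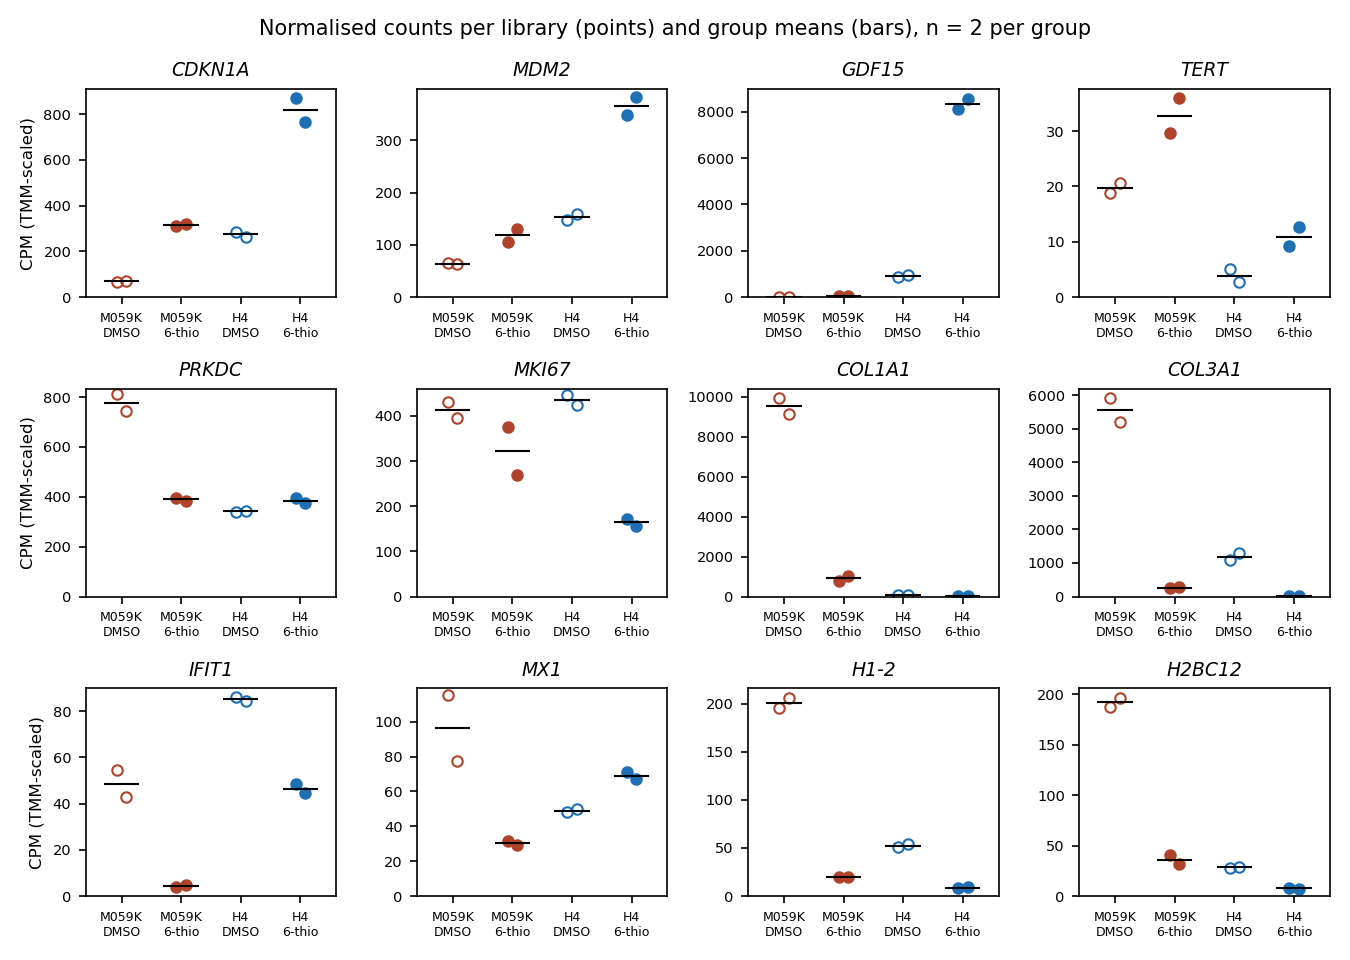
TMM-scaled CPM (linear axes from 0) of 12 genes in each of the 8 libraries, 2 points per group (open for DMSO, filled for 6-thio-dG) with a line at the mean. CDKN1A rose in both lines, from 69.5 to 316 CPM in M059K and from 274 to 818 CPM in H4, and PRKDC fell only in M059K, from 777 to 389 CPM.

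The interaction asks whether the lines responded differently. Positive values mean a higher response in H4, which can be a larger rise or a smaller fall than in M059K. It called 6480 of 14618 genes (44.3%), 3378 positive and 3102 negative. ACTA2 fell in M059K and not in H4 (22.6 ± 0.69 to 30.01 ± 3.41 CPM; difference 5.98 ± 0.14, SE). CA9 rose in M059K (19.9 ± 0.33 to 29.9 ± 5.00 CPM) and fell in H4 (difference -5.16 ± 0.27). PRKDC differed by 1.17 ± 0.10 and MKI67 by -1.05 ± 0.13. With library size alone the median over all genes moved by -0.14 and 2641 of 6784 called genes were positive (38.9%, against 52.1% with TMM).

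TERT differed by 0.76 ± 0.28 (SE) between the lines with an edgeR adjusted p of 0.0293. That p was 0.0774 without M059K DMSO replicate 2, 0.0719 without M059K 6-thio-dG replicate 1, 0.324 without H4 DMSO replicate 2, 0.217 without H4 6-thio-dG replicate 2 and 0.15 with the GC trend removed. MDM2 differed by 0.36 ± 0.12 with an adjusted p of 0.0165, which was 0.118 without M059K 6-thio-dG replicate 1, 0.0765 without H4 DMSO replicate 1, 0.0845 without H4 6-thio-dG replicate 2 and 0.146 with library size alone. GDF15 differed by 1.25 ± 0.12, CDKN1A by -0.61 ± 0.11 and SAMHD1 by 0.80 ± 0.14, while HPRT1 was not called (-0.27 ± 0.15, adjusted p 0.138). HPRT1 was called with library size alone (-0.41, adjusted p 0.0236) and without M059K 6-thio-dG replicate 1 (-0.48, adjusted p 0.00178).

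Of the lists, camera called 9 with a higher and 7 with a lower response in H4, of which TGF-beta and YAP targets were also called with an estimated correlation. For the lists called here, counts adjusted over the list alone matched those over all genes except where given. The p53, interferon, secretome and integrated stress response lists each hold 1 member at or under the floor in both M059K groups. The apoptosis, kinase inhibitor and cholesterol lists each hold 1 such member in both H4 groups. These members stay in the interaction counts, medians and tests, although no response of theirs can be measured in that line. TGF-beta and YAP targets were higher in H4 (16 of 23 positive, 4 negative and 3 not called, or 16 and 5 adjusted over the list alone, median 1.12, adjusted p 1.77e-12, and 0.0463 with an estimated correlation). Type I interferon response genes fell less in H4 than in M059K (27 of 37 positive, 1 negative, 9 not called, median 1.05, adjusted p 9.87e-15 and adjusted p = 0.233 with an estimated correlation), as did extracellular matrix genes (26 of 31 positive, 5 negative, 0 not called, median 1.23, adjusted p 3.20e-14 and adjusted p = 0.202 with an estimated correlation). Matrix genes also started lower in H4, with a median log2 difference in DMSO of -2.22. Replication and E2F targets had a lower response in H4 (1 of 46 positive, 32 negative, 13 not called, median -0.61, adjusted p 1.64e-10 and adjusted p = 0.240 with an estimated correlation). Hypoxia and glycolysis genes were lower (4 of 28 positive, 20 negative and 4 not called, or 4 and 22 adjusted over the list alone, median -0.57, adjusted p 3.17e-06 and adjusted p = 0.184 with an estimated correlation). G2/M and mitosis genes fell more in H4 (3 of 44 positive, 24 negative and 17 not called, or 3 and 26 adjusted over the list alone, median -0.39, adjusted p 7.65e-05 and adjusted p = 0.437 with an estimated correlation).

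Cholesterol synthesis genes also fell less in H4 than in M059K (17 of 25 positive, 0 negative and 8 not called, or 17 and 1 adjusted over the list alone, median 0.66, camera adjusted p 2.15e-05 and adjusted p = 0.202 with an estimated correlation). Ribosomal protein genes (31 of 50 positive, 2 negative and 17 not called, or 32 and 3 adjusted over the list alone, median 0.33) had an adjusted p of 0.000177 and adjusted p = 0.486 with an estimated correlation. Integrated stress response genes (18 of 30 positive, 4 negative, 8 not called, median 0.61) had 0.000268 and adjusted p = 0.233 with an estimated correlation. The secretome list (15 of 26 positive, 5 negative, 6 not called, median 0.58) had 0.00401 and adjusted p = 0.202 with an estimated correlation. DNA damage checkpoint genes (1 of 13 positive, 8 negative, 4 not called, median -0.65) had 0.00718 and adjusted p = 0.202 with an estimated correlation. Ribosome biogenesis genes (12 of 25 positive, 2 negative, 11 not called, median 0.18) had 0.0162 and adjusted p = 0.498 with an estimated correlation, and 0.0524 with library size alone. Homologous recombination genes (2 of 30 positive, 14 negative, 14 not called, median -0.36) had 0.0197 and adjusted p = 0.336 with an estimated correlation, and 0.0949 with the GC trend removed.

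Interaction calls of 3 lists were less secure. p53 targets (15 of 34 positive, 6 negative, 13 not called, median 0.36, camera adjusted p 0.0308 and adjusted p = 0.233 with an estimated correlation) were at 0.0510 without M059K 6-thio-dG replicate 1, 0.0525 with library size alone and 0.0518 with the stricter filter. Apoptosis regulators (6 of 27 positive, 12 negative, 9 not called, median -0.25, adjusted p 0.0381 and adjusted p = 0.233 with an estimated correlation) were at 0.0686 without M059K 6-thio-dG replicate 2, 0.0779 without H4 DMSO replicate 1, and 0.0547 and 0.0889 without H4 6-thio-dG replicate 1 or 2. Cyclin-dependent kinase inhibitors and pocket proteins were called lower (3 of 10 positive, 6 negative, 1 not called, adjusted p 0.0353 and adjusted p = 0.233 with an estimated correlation) with a median of -0.40 but a mean of 0.10. They were at 0.0607 without M059K DMSO replicate 2, 0.0529 without M059K 6-thio-dG replicate 1, 0.0837 and 0.0674 without H4 DMSO replicate 1 or 2, and 0.0661 and 0.073 without H4 6-thio-dG replicate 1 or 2.

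The lines shared part of the response. Genes higher in both numbered 2155 (1196.9 if the calls were independent) and genes lower in both 2496 (1339.2), while 443 rose in M059K and fell in H4 and 564 did the reverse. Under scaling by library size alone the balance turned over, with 3355 higher in both (2149.3 if independent) and 1731 lower in both (768.9). Of the 5658 genes called in both, 82.2% changed the same way, and 305 rose and 737 fell at least 2-fold in both. Across genes the log2 fold changes had Pearson's r of 0.407 and Spearman's rho of 0.456, and genes are not independent replicates. The lines share no control libraries.

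**Figure D3:**
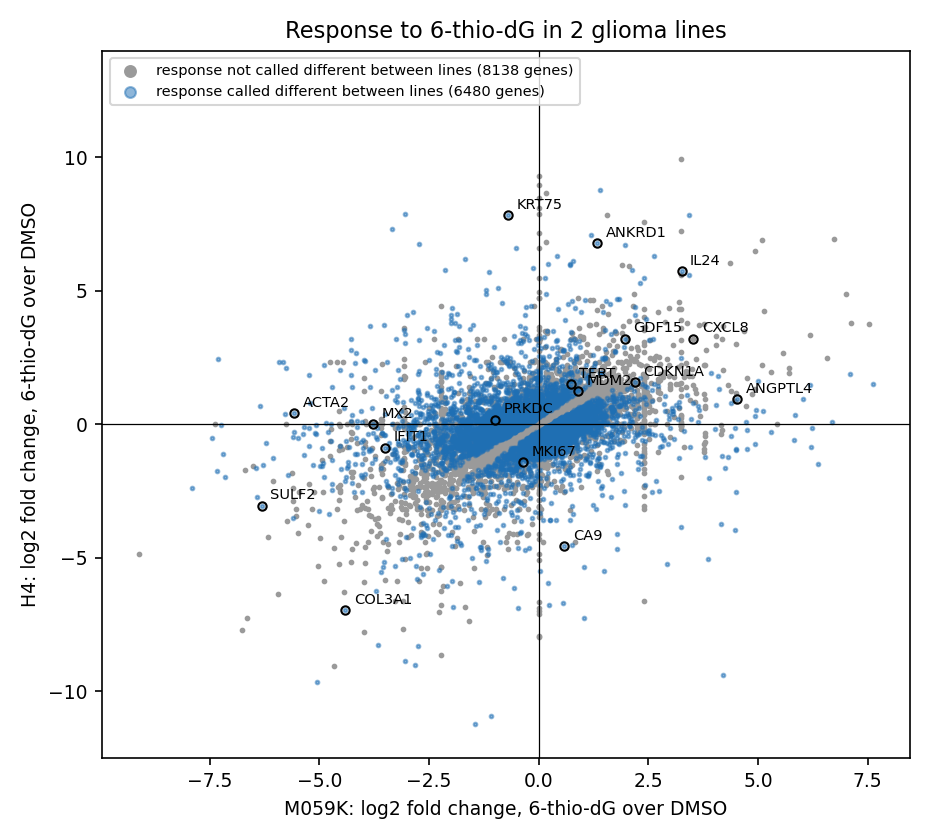
Log2 fold change, 6-thio-dG over DMSO, in M059K (horizontal) and H4 (vertical), 1 point per gene, blue for the 6480 genes whose response was called different between lines and grey for the rest. Across genes Pearson's r was 0.407, with CDKN1A (2.19 and 1.58) high in both lines and ACTA2 low only in M059K (-5.58).

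The last comparison asks how the lines differed before treatment, in DMSO. edgeR called 11022 of 14618 genes (75.4%), 5666 higher and 5356 lower in H4, with 3068 higher and 2312 lower at least 2-fold. The largest named differences included genes not detected in one line. MCTP2, a membrane protein, was at least 733-fold higher in H4, the homeobox gene MSX2 at least 716-fold and AJAP1 at least 676-fold, followed by AUTS2, ITGA8, MYH14 and B3GAT1 (at least 489, 384, 360 and 329-fold). CCND2, cyclin D2, had a counting interval of 2452 to 539800-fold higher. Smooth muscle gamma actin ACTG2 was at least 835-fold lower in H4, CHI3L1 at least 719-fold, the kinase inhibitor gene CDKN2B at least 545-fold and TMEM26 at least 267-fold, followed by TRIL, RNF212 and PNMA8A (at least 140, 130 and 128-fold). MYL9, a myosin light chain, was at 1134 ± 10.6 CPM in M059K and 0.35 ± 0.12 CPM in H4 (SD, n = 2). TERT was lower in H4 by a log2 difference of -2.34 ± 0.21 (SE), PRKDC by -1.19 ± 0.07 and SAMHD1 by -1.36 ± 0.10. GDF15 was higher by 5.83 ± 0.10, CDKN1A by 1.98 ± 0.08, MDM2 by 1.27 ± 0.09 and HPRT1 by 0.66 ± 0.10, and MKI67 was not called (0.08 ± 0.09, adjusted p 0.459). Line and any other difference between the cultures cannot be separated here.

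In DMSO, camera called 6 lists higher and 6 lower in H4, of which NRF2 targets were also called with an estimated correlation. Counts adjusted over the list alone were the same for all 12. NRF2 targets were higher (20 of 21, 0 lower, 1 not called, median 2.48, adjusted p 2.47e-29, and 0.0336 with an estimated correlation), with the aldo-keto reductases AKR1C1 at 8.80 and AKR1B10 at 8.28. Integrated stress response genes were higher (25 of 30, 3 lower, 2 not called, median 1.29, adjusted p 7.19e-09 and adjusted p = 0.0810 with an estimated correlation), as were p53 targets (26 of 34, 2 lower, 6 not called, median 1.03, adjusted p 2.68e-08 and adjusted p = 0.0810 with an estimated correlation). Proneural markers were higher (9 of 13, 2 lower, 2 not called, median 2.07, adjusted p 0.00233 and adjusted p = 0.0914 with an estimated correlation), with SOX11 at least 227-fold higher. Ribosomal protein genes (38 of 50 higher, 6 lower, 6 not called, median 0.43, adjusted p 0.00773) and nuclear oxidative phosphorylation genes (38 of 55 higher, 8 lower, 9 not called, median 0.48, adjusted p 0.0102) each had adjusted p = 0.721 with an estimated correlation.

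Extracellular matrix genes were lower in H4 in DMSO (30 of 31, 1 higher, 0 not called, median -2.22, camera adjusted p 1.52e-33 and adjusted p = 0.0690 with an estimated correlation), with COL1A2 at -11.36 and COL6A3 at 5.24. TGF-beta and YAP targets (19 of 23 lower, 4 higher, 0 not called, median -0.75, adjusted p 2.74e-06) also had adjusted p = 0.0690 with an estimated correlation. Cholesterol synthesis genes (24 of 25 lower, 1 higher, 0 not called, median -1.12, adjusted p 1.44e-08) and histone genes (14 of 16 lower, 1 higher, 1 not called, median -2.48, adjusted p 3.37e-05) had adjusted p = 0.0810 with an estimated correlation. Pericyte and fibroblast markers were lower (6 of 7, 0 higher, 1 not called, median -1.91, adjusted p 0.000824 and adjusted p = 0.0857 with an estimated correlation). Cyclin-dependent kinase inhibitors and pocket proteins were called lower (6 of 10, 4 higher, 0 not called, median -0.69, adjusted p 0.0227 and adjusted p = 0.184 with an estimated correlation). Their adjusted p was 0.248 and 0.269 without M059K DMSO replicate 1 or 2, 0.154 without M059K 6-thio-dG replicate 1, and 0.216 and 0.268 without H4 DMSO replicate 1 or 2.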

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

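The tests of fewer cells copying DNA, of the starting level of interferon genes, of histone variants, of admixed fibroblast-like cells and of unassigned reads were chosen after the results were seen, as was the removal of GC trends, and the other tests were planned. The results below stood out because a test of the difference found unequal responses of the lines, or because a signal lay in reads outside the gene counts. The fall of histone genes met neither rule and is weighed because these genes had the lowest medians of the called lists in both lines.

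The edgeR interaction called 6480 genes. Among gene lists, camera adjusted p-values for the difference, with medians of H4 minus M059K on the log2 scale, were 9.87e-15 for type I interferon response (1.05), 3.20e-14 for extracellular matrix (1.23), 1.77e-12 for TGF-beta and YAP targets (1.12), 2.15e-05 for cholesterol synthesis (0.66), 0.000177 for ribosomal proteins (0.33), 0.000268 for the integrated stress response (0.61), 0.00401 for the senescence secretome (0.58), 0.0162 for ribosome biogenesis (0.18) and 0.0308 for p53 targets (0.36). Lower responses in H4 had 1.64e-10 for replication and E2F targets (-0.61), 3.17e-06 for hypoxia and glycolysis (-0.57), 7.65e-05 for G2/M and mitosis (-0.39), 0.00718 for DNA damage checkpoints (-0.65), 0.0197 for homologous recombination (-0.36), 0.0353 for cyclin-dependent kinase inhibitors (-0.40) and 0.0381 for apoptosis regulators (-0.25). With an estimated correlation only TGF-beta and YAP targets kept an adjusted p under the threshold (0.0463). Leaving out single libraries ended the calls of p53 targets (highest adjusted p 0.051), apoptosis regulators (0.0889) and cyclin-dependent kinase inhibitors (0.0837).

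Among genes named by rule, the log2 difference (H4 minus M059K) was 8.54 for KRT75, 7.86 for SCUBE1, 5.98 for ACTA2, 5.46 for ANKRD1, 5.31 for SLAMF7, 5.09 for OMD, 4.06 for L1CAM, 3.65 for ESM1, 3.27 for SULF2, 2.49 for IL24, 2.17 for SERPINB2 and 2.09 for OLFML2B. It was -5.16 for CA9, -4.63 for NFE2, -4.48 for CMYA5, -3.89 for POSTN, -3.59 for ANGPTL4, -3.11 for PRRG4, -2.98 for PCDH18, -2.55 for COL3A1, -2.53 for LRRC17 and -0.76 for MAFF. The NFE2 value is as fitted and adds to a large fall in M059K. Counts of NFE2 after treatment in H4 may lie near 0, so the size of its difference is uncertain. Genes related to the drug differed by 1.25 (GDF15), 1.17 (PRKDC), 0.80 (SAMHD1), 0.76 (TERT), 0.36 (MDM2), -0.61 (CDKN1A) and -1.05 (MKI67). The TERT call ended without H4 DMSO replicate 2 (adjusted p 0.324), H4 6-thio-dG replicate 2 (0.217), M059K DMSO replicate 2 (0.0774) or M059K 6-thio-dG replicate 1 (0.0719). The MDM2 call ended without M059K 6-thio-dG replicate 1 (0.118), H4 6-thio-dG replicate 2 (0.0845) or H4 DMSO replicate 1 (0.0765).

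Other genes were at or near 0 counts in a group, so only the edgeR adjusted p of the difference is given. It was 3.89e-12 for PI15, 7.77e-11 for DCN, 1.03e-10 for KLHDC7B, 6.54e-06 for TP63, 3.44e-05 for TNFSF10, 0.000102 for KRT34, 0.000351 for PLEKHS1 and 0.00174 for CMKLR1. CMKLR1 was at least 19.1-fold lower after treatment in H4, and KLHDC7B had a counting interval of 1.74 to 65.4-fold lower in M059K. LCN2 (0.000986) and PCBP3 (0.035) were at or under the floor in both M059K groups, and TRIL (0.0298) and ACTG2 (0.000664) in both H4 groups. No response can be measured there, so these 4 adjusted p-values do not show unequal responses of the lines. The LCN2 call ended without M059K DMSO replicate 1 (adjusted p 0.9998). That of TRIL ended without H4 DMSO replicate 1 or 2 (0.0519 and 0.0511) or H4 6-thio-dG replicate 1 (0.9999). PCBP3 stayed under the threshold in 1 of the 8 leave-outs, without M059K 6-thio-dG replicate 2, with a highest adjusted p of 0.9998 without M059K 6-thio-dG replicate 1.

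Mean shares of reads not assigned to a gene were higher after treatment, although H4 6-thio-dG replicate 1 and H4 DMSO replicate 2 had the same share on genes (69.7%). Reads outside annotated genes made up 19.6 ± 0.42% (SD, n = 2) after treatment and 17.1 ± 0.60% in DMSO in M059K, while the H4 groups overlapped (26.2 ± 2.72% and 24.5 ± 0.59%). Reads without a unique position were 4.37 ± 1.12% against 3.33 ± 0.11% in M059K and 4.73 ± 0.62% against 3.74 ± 0.13% in H4. Reads matching more than 1 gene were 1.39 ± 0.01% against 1.29 ± 0.01% in M059K and 1.66 ± 0.05% against 1.5 ± 0.03% in H4. Treatment labels were permuted within each line, giving 36 arrangements. The exact one-sided adjusted p was 0.0417 for reads without a unique position, 0.0417 for reads matching more than 1 gene and 0.0556 for reads outside genes. The side was chosen after the shares were seen, and the exact two-sided adjusted p was 0.0833, 0.0833 and 0.111. A two-sided test of this kind cannot reach 0.05, since its smallest p is 0.0556, and the source of these reads was not tested.

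Histone genes fell in both lines (medians -2.49 and -2.92 as fitted, the latter -2.58 with members near 0 counts bounded or left out). With the GC trend removed the medians were -2.38 in M059K and -2.95 in H4. In M059K the trend was small, with a median change of 0.17 for genes lowest in GC content and -0.25 for those highest. Removing a trend of this size could not bring the list near 0 whatever the cause. The trend as measured does not account for the whole fall, and no more can be read from its removal. In H4 there was almost no trend to remove, with a rank correlation of the change with GC content of -0.0011. Fewer cells copying DNA is argued against only in M059K and weakly, because the replication list rose (median 0.56, SD of members 0.51). Its median lay 3.05 above that of the histone genes, but its camera call was lost with an estimated correlation (adjusted p 0.207). G2/M genes fell in M059K (37 of 44 lower, median -0.74, camera adjusted p 0.179 with an estimated correlation), which does not speak against fewer cells copying DNA. In H4 the replication list went both ways (median 0.065, SD of members 0.46) and does not decide. A weaker capture of RNA without a poly(A) tail stays open, since histone variants whose transcripts carry a tail fell less, with medians of -0.53 in M059K and -0.75 in H4 and 7 of 9 lower in each, and the way RNA was selected is not given. A biological response of histone transcripts to the drug may also account for the fall, and these transcripts do not measure DNA synthesis.

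Type I interferon genes fell in M059K (median -1.33), a call lost with an estimated correlation (adjusted p 0.179). With the GC trend removed the median was -1.38. The trend was small, with a median change of 0.17 for genes lowest in GC content and -0.25 for those highest. Removing a trend of this size could not bring the list near 0 whatever the cause. The trend as measured does not account for the whole fall, and no more can be read from its removal. With library size alone the median of the list was -1.07. That setting moves the median over all genes by only 0.25, too little to bring this list near 0 whatever the cause. The choice between these scalings does not account for the whole fall, and no more can be read from it. A higher starting level of the list in M059K was not seen. Before treatment the median difference (H4 minus M059K) was 0.36, with 21 of 37 members higher in H4 and 12 lower. Camera did not call the list (adjusted p 0.290), and a higher start of some members in M059K stays open. A biological difference of the lines in interferon signalling is a hypothesis found and tested on the same libraries. Passage and culture density are not given in the sources used here and stay open.

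Extracellular matrix genes fell in M059K (median -2.14). Removal of the GC trend gave -2.03. The trend was small, with a median change of 0.17 for genes lowest in GC content and -0.25 for those highest. Removing a trend of this size could not bring the list near 0 whatever the cause. The trend as measured does not account for the whole fall, and no more can be read from its removal. Library size alone gave -1.88. It moves the median over all genes by only 0.25, too little to bring this list near 0 whatever the cause. The choice between these scalings does not account for the whole fall. A few abundant genes taking much of the counts were not tested by it, since library size alone does not correct for them. The 10 most counted genes took 6.17 and 5.84% of gene counts in the M059K DMSO libraries. After treatment they took 2.97 and 2.95%. These small shares argue against a few abundant genes as the whole cause. Loss of admixed fibroblast-like cells cannot be told apart from a change within M059K, because the marker list fell (median -2.02, not called with an estimated correlation, adjusted p 0.0927) and M059K cells may make these transcripts themselves. All 7 tested markers were counted in M059K DMSO, 0 of them are in the matrix list, and the most abundant were LUM (733 to 180 CPM) and PDGFRB (217 to 19.2 CPM), while ABCC9 rose by 1.44. No sort or gate is stated, and a response of the cells to the drug stays a candidate explanation.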

How the results depend on the processing

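Removal of the GC trend was chosen after the data were examined, and the other alternatives were planned. No named gene that was called changed sign, and no list that camera called changed its test direction, under any alternative run. With library size alone the balance of higher and lower calls changed sides in M059K, H4 and the interaction, and some list medians changed sign, including that of mesenchymal glioma markers in M059K. Counting each named gene under each alternative, 376 results lost their call, 3 gained one in the reported direction and 10197 did neither. For lists these numbers were 134, 108 and 2144. Results that did neither include uncalled ones whose direction changed, even where the alternative called them. Kinase inhibitors in M059K, for example, went from up by camera (adjusted p 0.994) to down by fry (adjusted p 0.0247).

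Against a 1.5-fold change, glmTreat called 3751 genes in M059K, 2751 in H4, 2158 in the interaction and 6512 between lines in DMSO, a stricter question by construction. Of the 68 entries for genes with the largest changes, all kept their calls with RLE factors, library size alone, either filter, the block and DESeq2, and 66 kept them with glmTreat. With an estimated correlation, camera called 2 lists in M059K, 4 in H4, 1 in the interaction and 1 in DMSO. Fry, which does not compare a list with other genes, called 31, 32, 31 and 36.

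DESeq2 called 8640 genes in M059K, 7427 in H4, 5917 in the interaction and 10623 in DMSO. With the GC trend removed, edgeR called 9064, 8175 and 6321 in the treatment comparisons and their difference, and 3 M059K calls changed sign. In M059K the log2 fold change had a rank correlation with GC content of -0.149, and 0.0104 after removal, while in H4 it was -0.0011 before.

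Leaving out each library gave 7873 to 9062 genes in M059K, 6555 to 8626 in H4, 5453 to 6444 in the interaction and 10123 to 11469 in DMSO. No gene that stayed called with a library left out changed sign, and genes that lost their call were not checked for sign. The lone library of a group was assumed to vary like the other groups. Each leave-out also let more genes through the filter (14955 to 15015 tested, against 14618). A list call that ended with a library left out therefore need not depend on that library.

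A block for the replicate number called 9289, 8313, 6787 and 11122 genes. Deviations of libraries with the same number had correlations of 0.0111 in M059K and 0.0498 in H4, so the numbers give no pairing. The block ended list calls in M059K (secretome 0.121, mesenchymal glioma 0.173), H4 (NF-kB 0.125, proneural 0.328, pericyte and fibroblast 0.256), the interaction (apoptosis 0.0707, kinase inhibitors 0.106) and DMSO (kinase inhibitors 0.426), as adjusted p. It gained 3 list calls in the interaction and 2 in DMSO. Without the filter the same 8 calls ended (0.0853, 0.156, 0.236, 0.320, 0.240, 0.0800, 0.0896 and 0.371 in that order), as did early response in H4 (0.0564). Mesenchymal glioma in M059K was also not called with library size alone (0.117), the stricter filter (0.0541) or the GC trend removed (0.0503).

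The correlation of the responses across genes was 0.474 with the stricter filter and 0.355 to 0.381 with single libraries left out, against 0.407 as reported. Scaling by library size alone gave 3355 genes higher and 1731 lower in both lines, against 2155 and 2496, since it moves the median over all genes up by 0.25 in M059K and 0.11 in H4. Over 16 pairings of single libraries, r ran from 0.4095 to 0.4275 with an SD of 0.0057. These pairings used log CPM of the 14618 genes, and on that measure fewer libraries alone did not lower r. Fewer genes near the floor are tested with the stricter filter. Each leave-out, in contrast, tested more genes (14955 to 15015), and whether the added genes caused the shift was not tested.

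Among genes related to the drug, the causes of ended calls were not tested. They are given beside each gene with the library concerned. TERT in M059K was also not called by glmTreat (adjusted p 0.217). Changes of 1.25-fold were mostly missed in simulated data (28 to 32% recovered within a line or between lines, 8% for the interaction). Those data held far fewer changed genes than were called here, so these shares do not give the recovery in the real comparisons. Log2 changes called here were as small as 0.155 in M059K, 0.160 in H4 and 0.238 in the interaction.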

Other observations

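The symbol families and chromosome-end tests here were chosen after the data were examined, and the gene lists were fixed before.

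Lists not called in M059K had camera adjusted p-values from 0.0744 to 0.994. Checkpoint genes (0.0744) were at 0.0407 without M059K 6-thio-dG replicate 2, 0.0395 with library size alone and 0.0322 without the filter. Oxidative phosphorylation genes were at 0.0401 without M059K 6-thio-dG replicate 2, and proneural markers at 0.0451 with library size alone. Members higher and lower were 7 and 2 of 13 for DNA damage checkpoints, 5 and 4 of 13 for end joining, 3 and 1 of 7 for mismatch repair, 9 and 9 of 26 for purine and thiopurine metabolism, 3 and 5 of 10 for cyclin-dependent kinase inhibitors and 4 and 3 of 10 for nucleic acid sensing. They were 8 and 25 of 55 for oxidative phosphorylation, 13 and 10 of 28 for hypoxia and glycolysis, 7 and 10 of 21 for NRF2 targets (8 and 10 adjusted over the list alone), 6 and 12 of 23 for TGF-beta and YAP targets and 8 and 12 of 22 for lysosome and autophagy. For cell type markers they were 1 and 6 of 13 (proneural), 0 and 5 of 10 (astrocyte), 0 and 2 of 4 (oligodendrocyte), 0 and 4 of 8 (neuron), 2 and 1 of 7 (immune), 3 and 1 of 7 (endothelial) and 1 and 2 of 3 (epithelial). With library size alone the M059K medians of oxidative phosphorylation, NRF2, purine, nucleic acid sensing, TGF-beta and YAP and endothelial lists turned positive. Camera's direction was up against a negative median for kinase inhibitors (-0.46), purine metabolism (-0.01), nucleic acid sensing (-0.11), NRF2 targets (-0.17), lysosome (-0.37) and endothelial markers (-0.17, with a mean of 0.94).

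Lists not called in H4 had adjusted p-values from 0.0626 to 0.954, and lysosome genes were at 0.0349 with library size alone. Members higher and lower were 14 and 7 of 30 for homologous recombination (15 and 7 adjusted over the list alone), 2 and 3 of 13 for end joining, 2 and 1 of 7 for mismatch repair, 1 and 4 of 13 for checkpoints, 11 and 6 of 22 for telomere genes (median 0.20), 11 and 5 of 26 for purine metabolism (12 and 5), 12 and 9 of 27 for apoptosis, 2 and 4 of 10 for kinase inhibitors and 1 and 5 of 10 for nucleic acid sensing. They were 11 and 10 of 26 for the secretome (11 and 11), 4 and 22 of 55 for oxidative phosphorylation, 3 and 11 of 25 for cholesterol synthesis, 9 and 10 of 21 for NRF2 targets (10 and 10), 5 and 13 of 50 for ribosomal proteins (3 and 10), 11 and 7 of 22 for lysosome, 5 and 7 of 17 for mesenchymal glioma markers (6 and 8), 1 and 2 of 4 for oligodendrocyte, 1 and 4 of 8 for neuron, 1 and 2 of 7 for immune (1 and 1), 0 and 1 of 7 for endothelial (0 and 0) and 0 and 2 of 3 for epithelial markers. With library size alone the H4 medians of checkpoint, NRF2 and ribosomal protein genes turned positive. The secretome test pointed down against a median of 0.21, and the immune test up against -0.98, which was -0.33 with 1 member at or under the floor left out. The kinase inhibitor test pointed down against a fitted median of 0.05, which fell just below 0 with 1 such member left out.

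In the interaction the other lists had adjusted p-values from 0.0633 to 0.9997, with histone genes at 0.375 (median -0.95). Lysosome and autophagy genes (0.0633) were under 0.05 in all 8 leave-outs, from 0.0172 without H4 6-thio-dG replicate 2 to 0.048 without M059K DMSO replicate 1, and also without the filter (0.00907) and with the replicate block (0.0152). MHC class I genes (0.0689) were at 0.0413 without M059K DMSO replicate 2, 0.022 without M059K 6-thio-dG replicate 2, 0.0305 without H4 DMSO replicate 2, 0.0235 without H4 6-thio-dG replicate 2, 0.0186 without the filter and 0.045 with the block. Endoplasmic reticulum chaperones (0.0698) were at 0.0486, 0.022, 0.0342, 0.0316, 0.015 and 0.0402 under the same alternatives. Early response genes were at 0.0373 with the GC trend removed.

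In DMSO the other lists had 0.0794 to 0.958. Replication and E2F targets (0.134) were at 0.0446 without M059K DMSO replicate 1, 0.0142 without H4 DMSO replicate 1, 0.00981 without the filter and 0.0228 with the block. G2/M genes (0.0962) were at 0.0307, 0.0172, 0.00663 and 0.0182 under the same alternatives, and 0.0396 without M059K 6-thio-dG replicate 1. Hypoxia genes were at 0.0396 and 0.0477 without M059K 6-thio-dG replicate 1 or 2 and 0.0369 without H4 DMSO replicate 1, and the secretome at 0.0477 without M059K 6-thio-dG replicate 2.

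Of 128 families of genes with a shared symbol stem and at least 12 tested members, camera called 9 in M059K, and none had an adjusted p under 0.05 with an estimated correlation (0.538 for each). Collagens (4 of 29 higher, 21 lower, median -1.60, camera adjusted p 5.30e-10) and beta protocadherins (0 of 15 higher, 14 lower, median -1.73, 5.91e-07) fell, as did integrin alpha, semaphorin, ADAMTS and cadherin families. Zinc finger genes of the ZNF family rose (231 of 473 higher, 55 lower, median 0.39, 0.00147), as did USP and ATG families. In H4 keratins rose (10 of 15 higher, 1 lower, median 1.12, 1.44e-08; 0.801 with an estimated correlation), while semaphorins (3 of 19 higher, 16 lower, 4.58e-06), integrin alpha (0 of 12 higher, 9 lower, 0.000241), beta protocadherins (0 of 15 higher, 13 lower, 0.00435) and ADAMTS genes (2 of 18 higher, 8 lower, 0.00712) fell, each at 0.816 with an estimated correlation. The medians of these called families kept their sign when the shift of the median over all genes under library size alone was added. That is a shift of the fitted medians and not a test under that scaling. Collagens (median 0.72, 0.0053) and keratins (2.72, 4.89e-07) had higher responses in H4, and PPP (-0.31, 0.0284) and USP (-0.34, 0.0284) families lower ones, each at 0.894 with an estimated correlation.

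Because 6-thio-dG is used by telomerase, genes near chromosome ends were compared with others. The limit of 2 Mb was chosen after several distances were viewed. The camera p-value in limma, over 1050 genes near an end, was 0.621 in M059K (median -0.04, against 0 for genes farther away) and 0.601 in H4 (median 0.03, against -0.0025). In a linear model across genes with 4 covariates (GC content, gene span, exon length, mean expression), genes over 10 Mb from an end lay below those within 2 Mb, by a coefficient of -0.19 ± 0.04 (SE) in M059K and -0.12 ± 0.04 in H4. In M059K the medians without covariates ran the other way, so the direction there depends on the covariates. With the GC trend removed, camera placed genes near an end higher in both lines but did not call them (p 0.160 in M059K and 0.333 in H4). The model treats genes as independent, and the tests leave open whether position may matter.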
